A study of Homo sapiens with 4 samples.

How the data were processed

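Total RNA from 4 human samples was hybridised to whole-genome expression arrays with 54675 probe sets, 2 arrays of olfactory mesenchymal stem cells and 2 of transdetermined hematopoietic stem cells. Per the labels' protocols, RNA was purified with a column kit and labelled with biotin through in vitro transcription. The deposited values are log2 probe set levels, 1 column per array. Per the submitters' processing notes the affy package was used, and its version, the summarisation method and the normalization method are not given in the sources used here. That the scale is log2 was taken from the values, which lay between 2.08 and 14.92 on all arrays. The medians of the arrays lay between 5.32 and 5.38, so the values appear to have been normalized between arrays before they were deposited, and they were kept as deposited. No detection calls were used here, so a gene below the median of all genes on all 4 arrays is called dim (9013 genes, 57 of them past the threshold).

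Probe sets were named from the platform's annotation table. It gave 1 symbol for 41091 probe sets, several for 1801 and none for 11721, and 62 were array controls. Through the gene identifier, 41037 probe sets were matched to the RefSeq gene table of assembly GRCh38.p14, which was used for current names and gene order only, with 0 symbols changed. Probe sets with several symbols or none and the control probe sets were left out of the gene tests. So were 59 probe sets of Y-linked genes or of XIST and TSIX, while other X-linked genes were kept. Each of the 19740 remaining genes was measured by its probe set with the highest mean over the 4 arrays, a choice that does not use the groups, and 10511 genes had more than 1 probe set. All named genes past the threshold were checked for bright probe sets of opposite direction, and 0 had any. Of the 53 such genes with several probe sets, 16 rested on 1 of them, in that every other moved by under 33% of its change in the same direction, and in 15 of the 16 the others had means below the median of all genes. This check was added after the data were seen.

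Groups and replicate numbers were taken from the sample titles. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided), transdetermined minus olfactory, with no covariates, and p-values were adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. The fit had 2 residual degrees of freedom and 3.9 prior degrees of freedom, and the median standard error of a log2 change was 0.22. The smallest log2 change past the threshold was 0.97 in size. On simulated data with 200 changed genes of 19740 (20 simulations of 2 arrays against 2), the fit recovered 2.4% of genes changed by a log2 of 1, 73.6% at 2 and 97.9% at 4. In those simulations 4.9% of calls were false, and 0.1 calls were made on average with no change at all. A change of 2-fold was therefore mostly missed in these simulations. More genes passed in the data (805), which loosens the adjusted threshold, so recovery there can be higher.

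Before the data were examined, 29 gene lists with 775 entries were written from general knowledge of mesenchymal cells, blood cells and other cell types such a culture could hold, and 77 entries were not measured by a probe set with a single symbol. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists, and with an estimated correlation and with fry as alternatives. Members were also counted with p-values adjusted over the list alone. Some genes stand in more than 1 list. The rule for named genes was fixed at the same time. It took the 12 largest rises and the 12 largest falls past the threshold with the arrays of the groups apart and the higher mean above the median of all genes. To these it added the 4 members of each list with the smallest adjusted p, and always PTPRC, CD34, KIT, PROM1, RUNX1, GATA2, TAL1, SPI1, CXCR4, THY1, NT5E, ENG, CD44, VIM, COL1A1 and NES.

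The alternatives fixed beforehand were the replicate number as a block, quantile normalization, centring of each array on the median of its genes, genes above the median only, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts (names ending in _x_at or _s_at, called ambiguous here), eBayes with trend and robust, every probe set tested, a test against a fold of 1.5 (treat) and leaving out each array in turn. In the last of these the group left with 1 array is assumed to vary like the other. A crossed pairing of the replicates and a covariate for the balance of 5' and 3' signal were added after the data were seen. The covariate is the mean difference of the 5' and 3' control probe sets of actin and GAPDH, which was -0.58 and -1.35 on the olfactory arrays and -2.16 and -0.93 on the transdetermined arrays, so it did not separate the groups. It is not a measure of RNA integrity alone, because the same difference for the dap spike-in, an RNA added from outside, ran in the same order over the arrays (-3.12, -4.03, -5.25 and -3.45), although that for the thr spike-in did not (-4.11, -3.44, -4.75 and -4.07).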

Results

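Gene expression was measured on 4 human arrays in 2 groups. The first group was olfactory mesenchymal stem cells, a primary culture from the connective tissue layer beneath the smell epithelium of the nose (n = 2 arrays). The second was cells that the submitters call transdetermined hematopoietic stem cells (n = 2 arrays). The name implies that they had been driven towards the blood lineage, by a protocol that is not given in the sources used here. The comparison asked which genes differed between the 2 groups. Levels are log2 probe set values as deposited, and 19740 genes were tested, each through the probe set with the highest mean level. Changes are given as transdetermined minus olfactory. The number of arrays limits the precision, and nothing in the sources used here says that the replicates came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Nothing there says either whether both groups came from the same donors. Arrays of the same group had a Pearson correlation of 0.987 across genes in both groups, while arrays of different groups had correlations from 0.955 to 0.966. The SD of the log2 difference between arrays was 0.429 within either group and from 0.694 to 0.793 between groups.

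IBSP, SERPINB3, SERPINB4, SPP1 and PTPRC were among the genes with the largest fitted rises in the transdetermined cells. IBSP, the bone sialoprotein of mineralized matrix, rose from 2.98 ± 0.20 to 13.03 ± 0.14 (SD, n = 2 per group), a log2 change of 10.05 with a standard error of 0.21 (limma, adjusted p = 0.000128). Its other probe set rose by 5.10, and the mean of the 2 by 7.57 for IBSP (adjusted p = 0.000636), so the size of the rise depends on the probe set. SPP1, which encodes the secreted phosphoprotein osteopontin, rose by 8.02 ± 0.19 (SE; adjusted p = 0.00015). SERPINB3 and SERPINB4, inhibitors of proteases known from squamous epithelium, rose by 8.98 and 8.24, but they are near-identical copies whose probes can take up each other's RNA, so the share of each is uncertain. PTPRC, which encodes the leukocyte antigen CD45, rose by 6.64, from 3.59 ± 0.03 to 10.22 ± 0.50 (SD, n = 2; adjusted p = 0.000824).

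The other genes among the 12 largest rises were SCG2, a granin of secretory vesicles, at 6.90, CLDN20, of the claudin family of tight junction proteins, at 6.63, and PDK4, a kinase that restrains pyruvate dehydrogenase, at 6.53. They also included LINC01127 at 6.49, C7orf57 at 6.49, RGCC at 6.46 and IL1R2, the decoy receptor for interleukin 1, at 6.09. The call for RGCC was lost without olfactory replicate 1 (adjusted p = 0.0589) and without probe sets that can match several transcripts, where its change was 0.11 (adjusted p = 0.885). The olfactory means of these 12 genes ran from 2.56 to 4.57, below the median of all genes at 6.61, and no measure of background was used here. The sizes of these rises, PTPRC and SPP1 included, and their order therefore depend on the low end of the scale. SPP1, PDK4 and RGCC each rested on 1 of several probe sets, the others lying below that median on average with changes of at most 0.87.

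TNFRSF11B and NOG had the largest fitted falls. TNFRSF11B, which encodes osteoprotegerin, the decoy receptor for the osteoclast factor RANKL, fell by 5.34, to 6.17 ± 1.17 from 11.51 ± 0.69 (SD, n = 2; limma, adjusted p = 0.00993). NOG, which encodes the BMP antagonist noggin, fell by 5.26 ± 0.22 (SE), to 3.51 ± 0.07 (SD, n = 2; adjusted p = 0.000824). Of the 12 largest falls all but that of ID1 ended at transdetermined means from 3.51 to 6.47, below the median of all genes, so the size of these falls and the order of the genes depend on the low end of the scale. The lower group mean lay below that median in 46 of the 89 named genes past the threshold, 30 risen and 16 fallen, and the same holds for the size of their changes. LINC01085 fell by 4.60, the imprinted gene MEST by 4.58, the G protein regulator RGS7 by 4.47 and GJA5, a gap junction protein of arterial endothelium, by 4.36. The somatostatin receptor gene SSTR1 fell by 4.13, GPRC5A by 4.04, the keratin gene KRT19 by 3.94, RASGRP1 by 3.91 and ID1, a target of BMP signalling, by 3.87. PSG1 fell by 4.26, and as a member of a family of near-identical pregnancy glycoprotein genes its own share is uncertain. RASGRP1 was past the threshold with all arrays (adjusted p = 0.0143) and not without olfactory replicate 2 (adjusted p = 0.0715), and RGS7 was not when ambiguous probe sets were left out (log2 change -1.17, adjusted p = 0.0947). GJA5, SSTR1 and KRT19 each rested on 1 of 2 probe sets, the other lying below the median of all genes on average with a change of -0.72, -0.07 and -0.15.

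**Figure D1:**
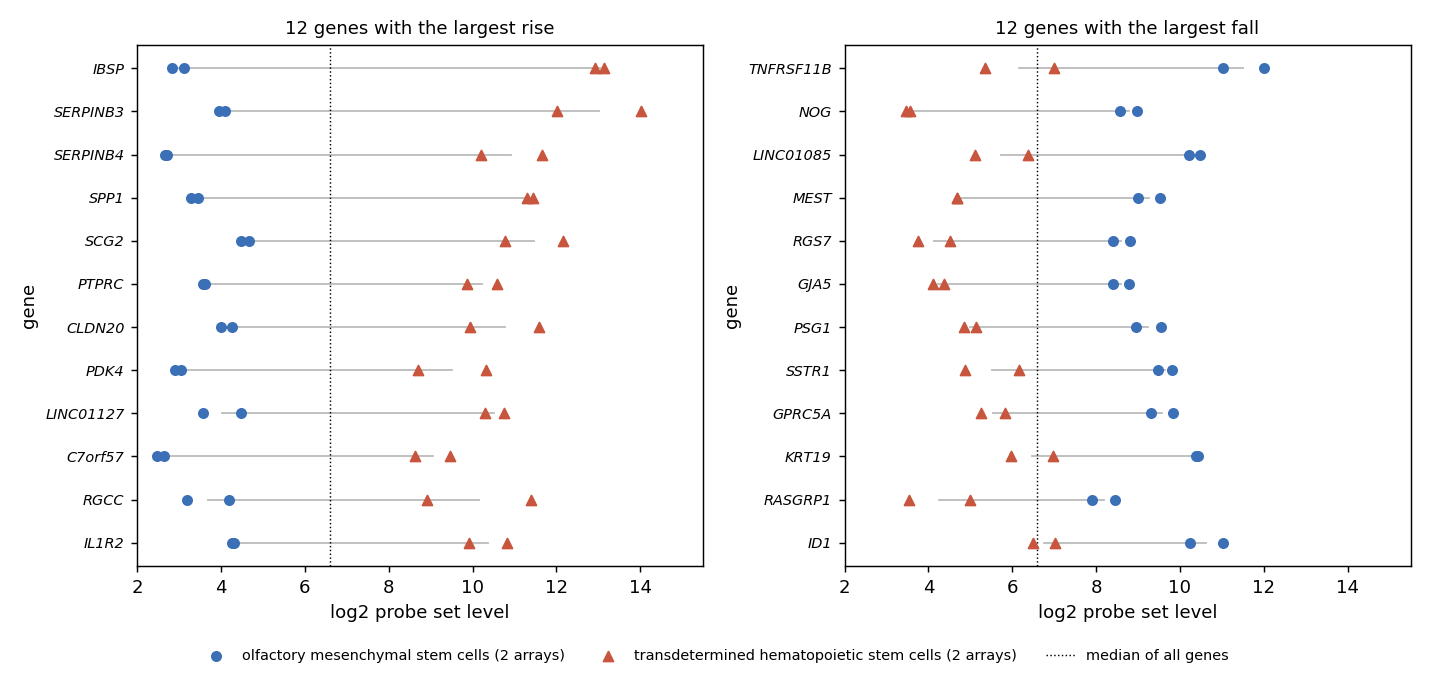
The 12 genes with the largest rise (left) and the 12 with the largest fall (right) among genes past the threshold, by log2 probe set level on the horizontal axis. Each circle is an olfactory array and each triangle a transdetermined array (2 each), the grey line joins the group means, and the dotted line is the median of all genes at 6.61. IBSP moved from a mean of 2.98 to 13.03. In every gene shown the 2 arrays of each group lay on the same side of both arrays of the other, as the rule for choosing them required.

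Across all genes, 805 of 19740 passed an adjusted p of 0.05, of which 492 rose and 313 fell in the transdetermined cells (limma with Benjamini-Hochberg adjustment). Before adjustment 3244 genes had a p under 0.05. Of the 805 genes, 797 changed at least 2-fold, 486 up and 311 down, and changes of at least 16-fold were 60 up and 9 down. All 805 had both arrays of one group above both arrays of the other. Groups of 2 arrays that overlap cannot pass this test, so that adds no support. Over all genes the arrangement was seen in 44.7% against 33.3% by chance. The share of calls that were higher was 61.1%, and 50.6% when each array was instead centred on the median of its genes, which moved the median log2 change of all genes from -0.02 to -0.13. The count depended on the arrays used: 282 genes passed without olfactory replicate 2, of which 262 were among the 805, and 409 passed without olfactory replicate 1, of which 333 were.

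Among genes of blood cells, PTPRC, HHEX and CD14 rose in the transdetermined cells, and most measured myeloid, lymphoid and erythroid markers were dim, meaning below the median of all genes on all 4 arrays. HHEX, a homeobox factor of early blood and endothelial development, rose by 5.27 ± 0.36 (SE; limma, adjusted p = 0.00228). CD14, the monocyte coreceptor for bacterial lipopolysaccharide, rose by 4.47, from 6.23 ± 0.11 to 10.70 ± 0.08 (SD, n = 2; adjusted p = 0.000824). The olfactory means of HHEX (6.01) and CD14 lay below the median of all genes, so the size of these rises depends on the low end of the scale. PTPRC and HHEX were the 2 of 29 measured genes of the hematopoietic stem and progenitor list that rose, 0 fell and 27 were not past the threshold, with 2 risen and 2 fallen when adjusted over the list alone (GATA2 and ANGPT1). ANGPT1, the angiopoietin 1 gene, had a change of -1.38 (adjusted p = 0.0936, and 0.0144 without transdetermined replicate 1). The list as a whole had a median change of 0.04 and did not differ from other genes (camera, adjusted p = 0.408).

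Single stem cell markers were measured as follows. CD34, the antigen used to select blood stem cells, was at 7.40 ± 1.26 in the transdetermined and 6.40 ± 0.43 in the olfactory cells (SD, n = 2), a difference that did not pass (limma, adjusted p = 0.494). Its transdetermined arrays differed by more than the group means did, and without transdetermined replicate 2 the change was 1.89 (adjusted p = 0.0344). KIT, the receptor for stem cell factor, had a change of -1.20 ± 0.76 (adjusted p = 0.539), and GATA2, a transcription factor of blood stem cells, one of -1.16 ± 0.25 (adjusted p = 0.0707). TAL1, SPI1, CXCR4 and PROM1 were dim, with changes of -0.26, -0.09, -0.24 and 0.10, the last turning to -0.01 with median centring. RUNX1 was not analysed here, because only probe sets with a single gene symbol were used.

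In the pan-leukocyte and myeloid list 3 of 27 measured genes rose (PTPRC, CD14 and CORO1A), 1 fell (RAC2), 23 were not past the threshold and 22 were dim, with the same counts of 3 and 1 when adjusted over the list alone. CORO1A, an actin-binding protein of leukocytes, had a change of 1.22 (adjusted p = 0.034), and RAC2, a small GTPase of blood cells, one of -1.15 (adjusted p = 0.0375). Both calls were lost when any 1 array was left out, with adjusted p up to 0.175 for CORO1A and 0.147 for RAC2, each without an olfactory array, and with the replicate block they were at 0.0582 and 0.0727, and with the added covariate at 0.0566 and 0.0564. The median of the list was -0.09 while its mean was 0.35 and camera's direction was up, without a call (adjusted p = 0.86). Of 26 lymphoid genes 0 passed in limma, also when adjusted over the list alone, 1 had an unadjusted p under 0.05, 22 were dim and the median change was -0.13 (camera, adjusted p = 0.408). IL7R, the interleukin 7 receptor, lay near the threshold with a change of 1.55 (adjusted p = 0.0534). It passed with genes above the median only (0.0398), the mean of all probe sets (0.0459), trend and robust (0.0158) and without transdetermined replicate 1 (0.0297), as well as under both alternatives added later (0.021 and 0.0175).

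The erythroid and megakaryocytic list had 1 gene risen, 1 fallen and 22 of 24 not past the threshold, and the same counts of risen and fallen when adjusted over the list alone (camera, median -0.17, adjusted p = 0.0911). TFRC, the transferrin receptor, fell by 2.12 (adjusted p = 0.0161), and PF4, a platelet chemokine, rose by 1.53 (adjusted p = 0.0409). Without olfactory replicate 2 the adjusted p was 0.0715 for TFRC and 0.189 for PF4, without olfactory replicate 1 it was 0.0719 and 0.0964, and without transdetermined replicate 2 it was 0.089 for PF4. With median centring PF4 was at 0.0582, and with the mean of all probe sets TFRC was at 0.0767. The whole list was called without olfactory replicate 1 (0.0175), without transdetermined replicate 1 (0.0476) and with the added covariate (0.015). Of 24 endothelial genes 0 rose, 2 fell (GJA5 and FLT1) and 22 were not past the threshold, and 1 rose and 2 fell when adjusted over the list alone (camera, median -0.05, adjusted p = 0.408). FLT1, a receptor for vascular endothelial growth factor, fell by 2.47 ± 0.25 (SE; adjusted p = 0.00738). EMCN, the gene added by the list alone, had a change of 0.95 (adjusted p = 0.0534, and 0.0164 with trend and robust).

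**Figure D2:**
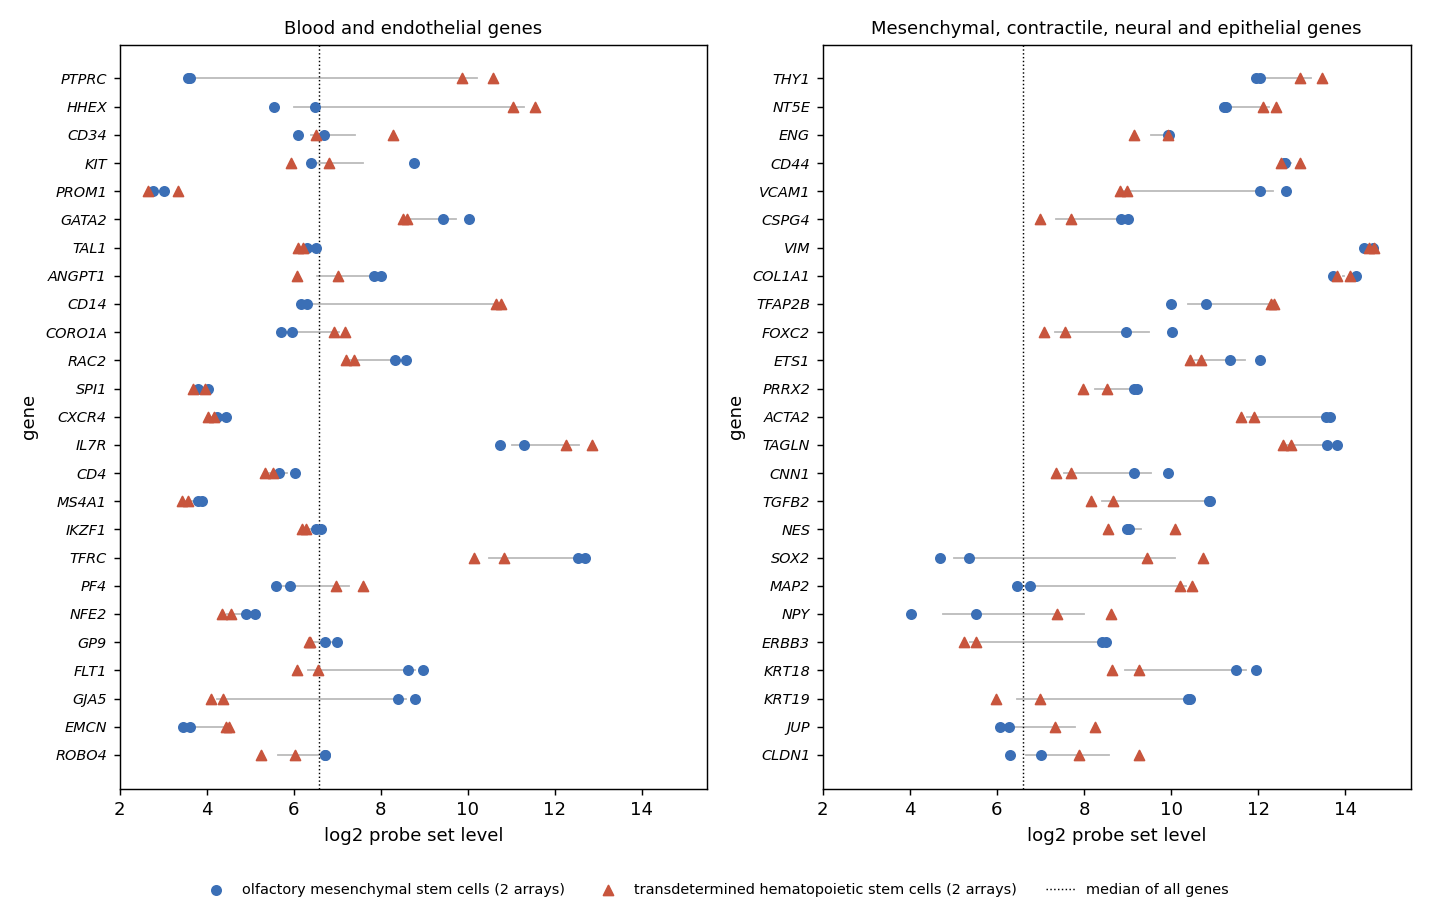
Log2 probe set level, on the horizontal axis, of named genes of blood and endothelial cells (left) and of mesenchymal, contractile, neural and epithelial cells (right). Circles are the 2 olfactory arrays, triangles the 2 transdetermined arrays, the grey line joins the group means and the dotted line is the median of all genes at 6.61. PTPRC, HHEX and CD14 moved from below the median of all genes to means of 10.22, 11.29 and 10.70, while the means of VIM were 14.53 and 14.61.

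Of the mesenchymal surface genes, VCAM1 and CSPG4 passed the test and THY1 and NT5E lay near the threshold. VCAM1, an adhesion molecule for leukocytes, was 10.8-fold lower in the transdetermined cells (limma, adjusted p = 0.0028). CSPG4, the proteoglycan NG2 of pericytes, had a change of -1.59 (adjusted p = 0.0415), a call lost without olfactory replicate 1 (adjusted p = 0.115), olfactory replicate 2 (0.186) or transdetermined replicate 2 (0.0767) and with quantile normalization (0.0547). These were the 2 fallen genes of 18 mesenchymal surface markers, 0 rose and 16 were not past the threshold, and 4 rose and 3 fell when adjusted over the list alone. The surface antigens THY1 (1.22, adjusted p = 0.0503) and NT5E (1.01, adjusted p = 0.056) were among those 4. Over all genes THY1 passed with genes above the median only (0.0413), the mean of all probe sets (0.0171), trend and robust (0.0127), without transdetermined replicate 1 (0.0326) and with the added covariate (0.0454), and NT5E with genes above the median only (0.0492) and trend and robust (0.0231). ENG and CD44 had changes of -0.40 and 0.14, and the filament gene NES one of 0.30. VIM had a change of 0.07 that turned to -0.05 with median centring, and COL1A1 one of -0.03 that turned to 0.04 with quantile normalization. The list had a median of 0.06, a mean of -0.13 and a camera direction of down that became up under both other scalings (adjusted p = 0.954).

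Genes of contractile cells shifted down as a list. Of 18 smooth muscle and myofibroblast genes 3 fell, 0 rose and 15 were not past the threshold, and 6 fell when adjusted over the list alone (camera, median -0.43, adjusted p = 0.000286). With an estimated correlation the list was not called (adjusted p = 0.628 with an estimated correlation). TGFB2, a transforming growth factor, fell by 2.46 ± 0.24 (SE; adjusted p = 0.00656), ACTA2, the smooth muscle actin, by 1.85 ± 0.20 (adjusted p = 0.0095) and the actin-binding protein gene CNN1 by 2.01 ± 0.31 (adjusted p = 0.0259). ACTA2 and CNN1 had adjusted p of 0.0575 and 0.0824 without olfactory replicate 2. ACTA2 was at 0.0574 with the mean of all probe sets, and CNN1 at 0.0509 and 0.0561 under the alternatives added later. TAGLN had a change of -1.04 (adjusted p = 0.0501) and passed under 5 alternatives, with adjusted p from 0.0104 with trend and robust to 0.0477 with quantile normalization.

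Matrix genes went both ways. Of 28 collagens and matrix proteins 3 rose, 2 fell and 23 were not past the threshold, with 6 risen and 3 fallen when adjusted over the list alone (camera, median 0.00, mean 0.12, adjusted p = 0.624). COL15A1, a basement membrane collagen, rose by 4.91 ± 0.28 (SE; adjusted p = 0.00155), and THBS2, an antiangiogenic matrix protein, fell by 2.01 ± 0.20 (adjusted p = 0.00732). Of 25 matrix crosslinking enzymes and proteases 3 rose, 2 fell and 20 were not past the threshold, with 5 and 4 when adjusted over the list alone. PLAT, the tissue plasminogen activator, rose by 2.77 ± 0.32 (adjusted p = 0.0112), and the stromelysin gene MMP3 fell by 3.19 ± 0.21 (adjusted p = 0.00213). That list had a median of -0.26, a mean of 0.02 and a camera direction of down that turned up with median centring (adjusted p = 0.706).

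Of 21 neural crest and ectomesenchyme genes 1 rose (TFAP2B, 1.94), 1 fell (FOXC2, -2.17) and 19 were not past the threshold, with 1 and 2 when adjusted over the list alone (camera, median -0.14, adjusted p = 0.101). The adjusted p was 0.0715 for TFAP2B and 0.101 for FOXC2 without olfactory replicate 2, and without transdetermined replicate 2 it was 0.0528 and 0.0842. With the mean of all probe sets it was 0.0577 and 0.0925, while the list itself was called (0.0333), and FOXC2 was at 0.0523 with quantile normalization and 0.0525 without ambiguous probe sets. Of 25 neural and glial genes 3 rose, 1 fell and 21 were not past the threshold, and the counts adjusted over the list alone were also 3 and 1. SOX2, a transcription factor of neural progenitors and pluripotent cells, rose by 5.07 ± 0.46 (SE; adjusted p = 0.00569) on 1 of its 4 probe sets, while the other 3 had low means and changes from 0.03 to 0.74. MAP2, a microtubule protein of dendrites, rose by 3.73 ± 0.22 (adjusted p = 0.00155). NPY, the neuropeptide Y gene, had a change of 3.23 (adjusted p = 0.0442) that did not pass without olfactory replicate 1 (0.102) or transdetermined replicate 1 (0.0587), nor with quantile normalization (0.0553) or without ambiguous probe sets (0.0589). ERBB3, a neuregulin receptor of Schwann cell precursors, fell by 3.08 ± 0.20 (adjusted p = 0.00205). The median of this list was -0.14, its mean 0.26 and camera's direction down (adjusted p = 0.756).

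SOX2, on the single probe set described above, was the 1 of 18 pluripotency genes that rose, 0 fell and 17 were not past the threshold, with 1 and 2 when adjusted over the list alone. The median of that list was -0.05, its mean 0.03 and camera's direction down (adjusted p = 0.624). KLF4 lay near the threshold with a change of -2.43 (adjusted p = 0.0521). It passed with quantile normalization (0.0417), median centring (0.0476), genes above the median only (0.0348), trend and robust (0.019), without olfactory replicate 2 (0.0191) and with either pairing as a block (0.0236 and 0.0348). MYC had a change of -1.40 (adjusted p = 0.0675) and passed with trend and robust (0.0346). Of 21 epithelial genes 0 rose, 2 keratin genes fell (KRT19, and KRT18 by 2.78 with adjusted p = 0.00773) and 19 were not past the threshold, with 2 risen and 2 fallen when adjusted over the list alone (camera, median -0.24, adjusted p = 0.0911). The 2 risen there were the junction genes JUP at 1.62 (adjusted p = 0.0581 over all genes) and CLDN1 at 1.91 (0.111). JUP passed with the replicate block (0.0468), genes above the median only (0.0424), trend and robust (0.0338), without transdetermined replicate 2 (0.0121) and under both alternatives added later (0.0424 and 0.0487). CLDN1 passed with the replicate block (0.0141) and without transdetermined replicate 1 (0.0124). Of 21 HOX genes 0 passed over all genes or adjusted over the list alone and 20 were dim, and 0 had an unadjusted p under 0.05 (limma and camera, median -0.07, adjusted p = 0.624).

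Genes induced by interferon formed the list with the clearest shift, up in the transdetermined cells. Of 26 measured genes 14 rose, 0 fell and 12 were not past the threshold, 19 rose when adjusted over the list alone, and 24 of 26 were higher (camera, median 2.33, adjusted p = 4.84e-18). That p rests on the preset correlation of 0.01, while the correlation estimated for this list was 0.496. With the estimate the list was not called (camera, adjusted p = 0.496), so the small p overstates the evidence if the estimate holds. MX1, a GTPase that restricts influenza virus, rose 59.2-fold (log2 5.89 ± 0.35, SE; adjusted p = 0.00164), OAS1, a sensor of double-stranded RNA, rose 31.1-fold (adjusted p = 0.00147), IFI27 rose 13.4-fold and OAS3 rose 8.63-fold. The olfactory means of MX1 (4.90), OAS1 (4.27) and OAS3 (5.95) lay below the median of all genes, so the size of their folds depends on the low end of the scale, and the other probe set of OAS3 had a low mean and a change of 0.42. The list's median was 0.68 higher on transdetermined replicate 2 than on replicate 1.

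Genes of antigen presentation by MHC molecules also shifted up. Of 21 measured genes 6 rose, 0 fell and 15 were not past the threshold, and 8 rose when adjusted over the list alone (camera, median 0.41, adjusted p = 0.000358; adjusted p = 0.496 with an estimated correlation). HLA-B, HLA-C and HLA-F, class I genes, had changes of 1.48, 1.45 and 1.56, and CD74, the invariant chain of class II, one of 1.81 (limma, adjusted p from 0.0134 to 0.0287). The HLA genes are close copies, so their separate values are uncertain, and all 4 calls were lost when either olfactory array was left out, with adjusted p from 0.0689 for HLA-F to 0.145 for CD74. The calls for HLA-B and HLA-C were also lost without transdetermined replicate 2 (0.0683 and 0.0709). HLA-F was at 0.0684 without ambiguous probe sets, and CD74, which rested on 1 of 3 probe sets, at 0.24 with the mean of all probe sets and 0.0528 and 0.0592 under the alternatives added later.

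Inflammatory cytokines and NF-kB targets had a lower median in the transdetermined cells, a call that depended on the arrays and the settings, and the 2 olfactory arrays differed in them. The list's median was 1.49 higher on olfactory replicate 2 than on olfactory replicate 1. Of 26 measured genes 2 rose, 2 fell and 22 were not past the threshold, with 3 and 5 when adjusted over the list alone (camera, median -0.91, adjusted p = 0.0298; adjusted p = 0.892 with an estimated correlation). The direction turned up, without a call, when olfactory replicate 2 was left out (adjusted p = 0.429), and without transdetermined replicate 1 the call was lost (adjusted p = 0.0586). It was also lost with median centring (0.169) and without ambiguous probe sets (0.102). TNFAIP6, a hyaluronan-binding protein, rose by 4.98 ± 0.37 (SE; adjusted p = 0.0031), and VCAM1 fell as given above. The pentraxin gene PTX3 had a change of -3.46 (adjusted p = 0.0162, and 0.0551 without olfactory replicate 2), and IL1B, the interleukin 1 beta gene, one of 2.14 (adjusted p = 0.0358, and 0.0571 without olfactory replicate 1, 0.0692 without transdetermined replicate 2, 0.0501 with the mean of all probe sets, and 0.0502 and 0.0807 under the alternatives added later).

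Members of the TGF-beta and BMP list went both ways, and the call for the list as a whole depended on the settings. Of 23 measured genes 4 rose, 7 fell and 12 were not past the threshold, with 5 and 11 when adjusted over the list alone (camera, median -0.45, adjusted p = 0.039; adjusted p = 0.892 with an estimated correlation). ID1 and NOG were among the fallen, with SMAD6, an inhibitor of BMP signalling, at -2.03 ± 0.19 (SE; limma, adjusted p = 0.00569). SMAD6 rested on 1 of 4 probe sets and was at -0.11 when ambiguous probe sets were left out (adjusted p = 0.938) and -0.61 with the mean of all probe sets (0.193). TGFBR2, a TGF-beta receptor, rose by 3.30 ± 0.22 (adjusted p = 0.00216) and HEY1, a Notch target, by 3.68 ± 0.41 (adjusted p = 0.0101). The call for the list was lost without olfactory replicate 2 (adjusted p = 0.212) and without transdetermined replicate 1 (adjusted p = 0.136). It was also lost with median centring (0.169), genes above the median only (0.18), the mean of all probe sets (0.0757), without ambiguous probe sets (0.657) and under both alternatives added later (0.0642 and 0.0875).

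Notch and Wnt genes shifted up. Of 30 measured genes 4 rose, 1 fell and 25 were not past the threshold, with 9 and 2 when adjusted over the list alone (camera, median 0.29, adjusted p = 0.00609; adjusted p = 0.496 with an estimated correlation). The call was lost without ambiguous probe sets (0.0923). Besides HEY1 the risen genes were AXIN2, a feedback target of Wnt signalling, at 3.10 (adjusted p = 0.0114), RSPO3, an amplifier of Wnt signalling, at 2.79 (adjusted p = 0.0168) and the dim gene DKK2, a Wnt antagonist, at 1.99 (adjusted p = 0.0396). Their adjusted p were 0.0593, 0.0699 and 0.158 without olfactory replicate 2, and without olfactory replicate 1 those of RSPO3 and DKK2 were 0.0721 and 0.128. AXIN2 rose on 1 of its 4 probe sets, while the other 3 had low means and changes from -0.24 to 0.12, and with the mean of all probe sets its change was 0.74 and not past the threshold (0.0944). DKK2 rested on 1 of 2 probe sets and was at 0.142 with their mean and 0.0513 without ambiguous probe sets.

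Of 24 hematopoietic cytokines and niche factors 3 rose, 2 fell and 19 were not past the threshold, with 6 and 5 when adjusted over the list alone (camera, median 0.01, adjusted p = 0.408). SPP1, a component of the bone marrow niche, was the largest. PTN, a growth factor of that niche, had a change of 3.08 ± 0.35 (SE; limma, adjusted p = 0.0105). Its other ambiguous probe sets rose by 2.73 and 3.13. When ambiguous probe sets were left out the change was -0.03, on a probe set with a mean of 4.58, below the median of all genes. The call for PTN was lost without olfactory replicate 2, where the change was 2.85. CXCL12, the chemokine that retains blood stem cells in marrow, had a change of -1.47 (adjusted p = 0.0303), and the dim gene IL7 one of 1.54 (adjusted p = 0.0144). Without olfactory replicate 2 these had adjusted p of 0.113 and 0.0856, without olfactory replicate 1 they had 0.122 and 0.0558, and CXCL12 had 0.0665 without transdetermined replicate 1. Of 22 osteogenic, chondrogenic and adipogenic genes 2 rose (IBSP and SPP1), 2 fell (LEP and CEBPB) and 18 were not past the threshold, with 2 and 3 when adjusted over the list alone (camera, median 0.01, adjusted p = 0.706, and 0.0439 with genes above the median only). LEP, the adipocyte hormone leptin, had a change of -3.12 (adjusted p = 0.0139, and 0.0544 without olfactory replicate 2). CEBPB, a factor of adipocyte and macrophage differentiation, had one of -1.36 (adjusted p = 0.0193, with 0.0814 without olfactory replicate 1, 0.107 without olfactory replicate 2 and 0.0518 without transdetermined replicate 1).

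Cholesterol synthesis and lysosome genes shifted up. Of 18 cholesterol synthesis genes 2 rose, 0 fell and 16 were not past the threshold, 12 rose when adjusted over the list alone and 16 of 18 were higher (camera, median 0.72, adjusted p = 2.81e-07; adjusted p = 0.496 with an estimated correlation). TM7SF2, a sterol reductase, rose by 2.30 ± 0.19 (SE; limma, adjusted p = 0.00467). HSD17B7 had a change of 1.11 (adjusted p = 0.0491) that did not pass when any 1 array was left out, with adjusted p up to 0.229 without olfactory replicate 2, nor with median centring (0.0639), the replicate block (0.0877) or the alternatives added later (0.0577 and 0.0679). Of 22 lysosome and autophagy genes 2 rose, 0 fell and 20 were not past the threshold, and 5 rose when adjusted over the list alone (camera, median 0.41, adjusted p = 9.76e-05; adjusted p = 0.496 with an estimated correlation). The risen genes were CTSZ, a cathepsin, at 1.70 (adjusted p = 0.0133) and NEU1, the lysosomal sialidase, at 1.64 (adjusted p = 0.0113), with 0.0715 and 0.0699 without olfactory replicate 2. The other probe set of CTSZ had a low mean and a change of 0.20.

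The hypoxia and glycolysis list, the unfolded protein and ATF4 response list and the heat shock and metallothionein list shifted down. Of 27 hypoxia and glycolysis genes 6 fell, 0 rose and 21 were not past the threshold, and 8 fell when adjusted over the list alone (camera, median -0.39, adjusted p = 8.4e-06; adjusted p = 0.496 with an estimated correlation). CA12, a carbonic anhydrase, fell by 2.32 ± 0.18 (SE; limma, adjusted p = 0.00392), and the hexokinase gene HK2 fell by 2.46 ± 0.32 (adjusted p = 0.0158) on 1 of 3 probe sets, the others changing by -0.61 and -0.53. Of 25 unfolded protein and ATF4 response genes 5 fell, 0 rose and 20 were not past the threshold, with 10 fallen and 3 risen when adjusted over the list alone (camera, median -0.32, adjusted p = 0.0087; adjusted p = 0.892 with an estimated correlation). NUPR1, a stress-induced chromatin protein, fell by 2.83 ± 0.23 (adjusted p = 0.00404), and PSAT1, an enzyme of serine synthesis, fell by 2.14 ± 0.21 (adjusted p = 0.0068). The call for that list was lost without olfactory replicate 1 (adjusted p = 0.468), without transdetermined replicate 1 (adjusted p = 0.0878), without ambiguous probe sets (0.0523) and with the added covariate (0.255). Of 21 heat shock and metallothionein genes 2 fell, 0 rose and 19 were not past the threshold, and 3 fell when adjusted over the list alone (camera, median -0.55, adjusted p = 9.76e-05; adjusted p = 0.496 with an estimated correlation). The call for this list was lost without ambiguous probe sets (0.0894). The fallen genes were HMOX1, a heme oxygenase of the oxidative stress response, at -2.77 (adjusted p = 0.0192) and TXNRD1, a thioredoxin reductase, at -1.66 (adjusted p = 0.0181, with 0.0721 without olfactory replicate 1 and 0.0927 with the mean of all probe sets). The gene added when adjusted over the list alone was HSPB8, a small heat shock chaperone, at -1.09 (adjusted p = 0.0781 over all genes, and 0.0486 without transdetermined replicate 2), and 19 of the 21 members were lower.

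Cell cycle and ribosomal protein lists were called without any single gene passing. Of 37 cell cycle and proliferation genes 0 passed over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05 and 33 were higher (limma and camera, median 0.32, adjusted p = 0.017; adjusted p = 0.892 with an estimated correlation). The list's median was 0.95 lower on olfactory replicate 2 than on olfactory replicate 1, and without olfactory replicate 2 the direction turned down without a call (adjusted p = 0.102), while without transdetermined replicate 1 it was up without a call (adjusted p = 0.185), as it was with genes above the median only (0.0827). CCNE2, a cyclin of S phase entry, had a change of 1.42 (adjusted p = 0.119, 0.0456 without olfactory replicate 1 and 0.048 with the replicate block). Of 29 ribosomal protein genes 0 passed in either count, 1 had an unadjusted p under 0.05 and 26 were lower (limma and camera, median -0.15, adjusted p = 0.0241; adjusted p = 0.892 with an estimated correlation). That call was lost without olfactory replicate 2 (adjusted p = 0.156), without transdetermined replicate 2 (adjusted p = 0.343), with quantile normalization (adjusted p = 0.121), with the replicate block (0.0585) and without ambiguous probe sets (0.0576). Of 22 p53 target and senescence genes 1 rose (TP53I3, 1.60), 1 fell (GADD45A, -1.24) and 20 were not past the threshold, with the same counts when adjusted over the list alone (camera, median 0.09, adjusted p = 0.751). TP53I3 had an adjusted p of 0.0556 without olfactory replicate 1, 0.121 without olfactory replicate 2 and 0.061 without transdetermined replicate 2, and GADD45A one from 0.0517 to 0.192 when any 1 array was left out and of 0.0559 with the replicate block, 0.0568 with the crossed pairing and 0.0686 with the added covariate.

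**Figure D3:**
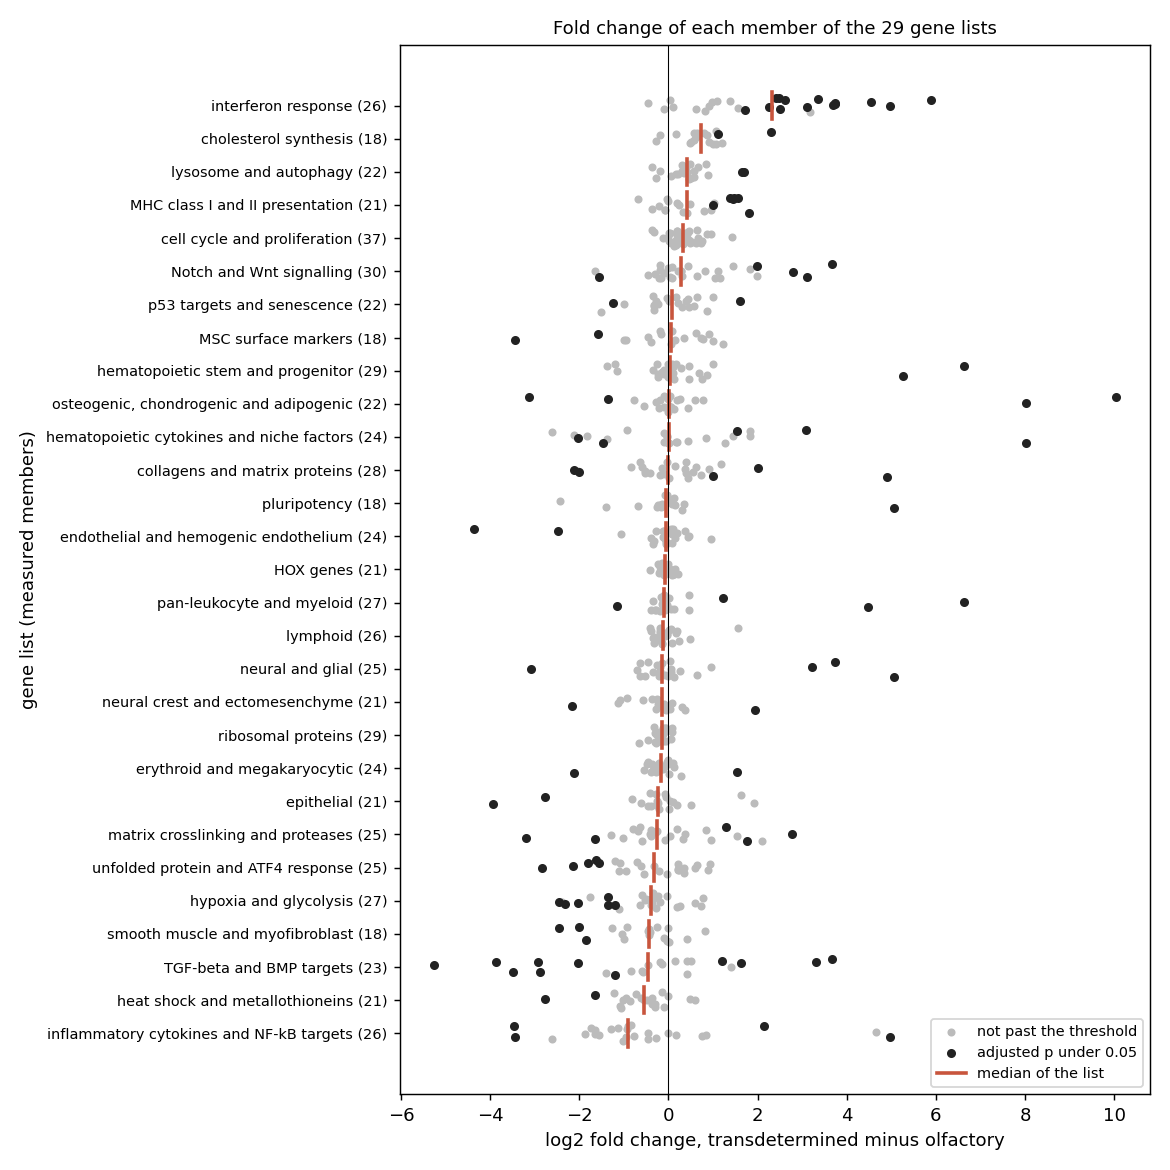
Log2 change (transdetermined minus olfactory, horizontal axis) of each measured member of the 29 gene lists (vertical axis, with the number of measured members in brackets). Each point is a gene, black where its adjusted p was under 0.05 and grey otherwise, and the bar is the list's median. The interferon response list lay highest with a median of 2.33 and the inflammatory list lowest with -0.91, a list whose direction turned without olfactory replicate 2.

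Of the 29 lists, 13 were called by camera with a preset correlation of 0.01, 6 up and 7 down. With an estimated correlation 0 of the 13 held, and the smallest adjusted p was 0.496. Among the 13 called lists the estimate lay above the preset value in all but the heat shock list. It ran from 0.018 for Notch and Wnt to 0.876 for cell cycle, with 0.496 for interferon and 0.66 for the inflammatory list. Where it lay far above the preset, the p with the preset can overstate the evidence. For the heat shock list it was -0.018, below the preset value. A larger correlation therefore did not cost the heat shock list its call. With 4 arrays that version rests on 2 residual degrees of freedom, so a call lost there is weak evidence against a list. The fry test, which asks whether a list's genes move one way on balance, called 0 lists (smallest adjusted p = 0.0822), and its version for changes in either direction called 22.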

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

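Probe sets with no gene symbol took no part in the comparison of genes. Of 11721 such probe sets, tested in a fit of their own, 5 were higher and 2 lower in the transdetermined cells at an adjusted p of 0.05 (limma), and the largest log2 change among the higher ones was 4.75.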

How the results depend on the processing

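The crossed pairing and the covariate for 5' and 3' signal were chosen after the data were seen, and the other alternatives before the data were examined. Of the 89 named genes past the threshold, 47 passed under every alternative planned for single genes in which they were measured, among them IBSP, SPP1, PTPRC, CD14, HHEX, MX1, OAS1, NOG, ID1, VCAM1 and TGFBR2. Of these examples SPP1, ID1 and VCAM1 have only ambiguous probe sets, so they were not measured when such probe sets were left out. NOG, with a mean of 6.14, was not among the genes above the median. The test against a fold of 1.5 and the test of every probe set were planned for the counts of genes only and were not run gene by gene. PTN was the 1 called gene that changed sign, at -0.03 without ambiguous probe sets. There another probe set stands for the gene, with a mean of 4.58, below the median of all genes. Sign changes with neither value past the threshold were counted as unchanged (at most 4 of 140 named genes and 5 of 29 lists in any setting). Without olfactory replicate 2, 36 of the 89 lost their call, the most of any alternative run on them, and 28 did without olfactory replicate 1. No measure of background was used here, so how far low signal limits the calls among dim genes is not known. The cause was not tested for any list whose call changed, except that leaving out an array also leaves fewer samples.

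The count of 805 genes was 770 with quantile normalization (744 shared), 813 with median centring (724 shared), 720 with genes above the median only, 673 with the mean of all probe sets, 554 without ambiguous probe sets, 667 when every probe set was tested and 1051 with trend and robust. Against a fold of 1.5 it was 314, of which 210 were higher and 104 lower. With 1 array left out the count, and that of genes at least 2-fold changed, ran from 282 to 853, with 182 to 581 higher and 100 to 272 lower. The replicate block called 726 genes, 633 of them shared, and of all lists it moved only the ribosomal proteins across the threshold (adjusted p = 0.0585). The deviations of same-numbered arrays had a correlation of -0.32 across genes, so they tended to run in opposite directions. Olfactory replicate 1 thus tended to deviate with transdetermined replicate 2, and each had the higher 5' minus 3' control difference of its group (-0.58 and -0.93). Genes with an unadjusted p under 0.05 (limma) numbered 3244 in the main fit and 2558 with the replicate block. They numbered 4333 with the crossed pairing and 4400 with the 5' and 3' signal covariate. Apart from that covariate, what the arrays share in this way was not tested. With the crossed pairing as a block 968 genes were called, 722 of them shared, and the TGF-beta and BMP list was not (adjusted p = 0.0642). The 5' and 3' signal covariate gave 1054 genes, 691 of them shared.

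With the estimated correlation and with fry, in that order, the adjusted p were 0.496 and 0.0822 for each of the interferon, MHC, cholesterol, lysosome and heat shock lists, 0.496 and 0.115 for each of the hypoxia and the Notch and Wnt lists, and 0.628 and 0.12 for smooth muscle. They were 0.892 and 0.657 for the inflammatory list, 0.892 and 0.705 for cell cycle, 0.892 and 0.244 for the unfolded protein list, 0.892 and 0.226 for TGF-beta and BMP, and 0.892 and 0.431 for ribosomal proteins. With 1 array left out the adjusted p ran from 6.89e-10 to 0.429 for the inflammatory list and from 5.33e-12 to 0.185 for cell cycle, and both turned direction without olfactory replicate 2 (0.429 and 0.102). It ran from 1.65e-06 to 0.468 for the unfolded protein list, from 0.00343 to 0.212 for TGF-beta and BMP, from 0.00967 to 0.343 for ribosomal proteins and from 0.0175 to 0.627 for the erythroid list, which was called without olfactory replicate 1 and without transdetermined replicate 1 (0.0476).

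Median centring gave 0.169 for both the inflammatory and the TGF-beta and BMP lists, and quantile normalization 0.121 for ribosomal proteins. Without ambiguous probe sets the adjusted p were 0.102 for the inflammatory, 0.0523 for the unfolded protein, 0.0894 for the heat shock, 0.657 for the TGF-beta and BMP, 0.0923 for the Notch and Wnt and 0.0576 for the ribosomal list. Genes above the median only gave 0.0827 for cell cycle, 0.18 for TGF-beta and BMP and a call of 0.0439 for the osteogenic, chondrogenic and adipogenic list. The mean of all probe sets gave 0.0757 for TGF-beta and BMP and a call of 0.0333 for the neural crest list. The 5' and 3' signal covariate gave 0.255 for the unfolded protein list, 0.0875 for TGF-beta and BMP and a call of 0.015 for the erythroid list.

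The ratio of the spread between groups to that within groups was 1.69, 1.82 for genes above the median only and 1.71 with quantile normalization.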

Other observations

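The tests of a leukocyte admixture, of single probe sets, of 5' signal and of interferon gamma were chosen after the result was seen, as were the gene families and the arrays described here. The PSG family of pregnancy glycoprotein genes had 7 of 9 measured members fallen, 2 not past the threshold and a median change of -1.54 (limma). PSG2 fell by 3.86 (adjusted p = 0.00182) and PSG5 by 1.41 (adjusted p = 0.0221). These genes are near-identical, so probes can take up the RNA of more than 1 and the members cannot be counted as independent. Of 4 AKR1C genes, reductases of steroids and carbonyl compounds, 3 rose, with AKR1C3 at 4.44 (adjusted p = 0.0382), and of 11 SERPINB genes 3 rose, SERPINB3, SERPINB4 and SERPINB7 (2.79, adjusted p = 0.00404). Whether probes of these related genes take up each other's RNA was not tested, so the rises within a family may not be separate.

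Olfactory replicates 1 and 2 stood apart in cytokine genes. CXCL8, a neutrophil chemokine, was at 8.28 on replicate 1 and 13.18 on replicate 2, PTGS2, the inducible cyclooxygenase, at 5.98 and 11.18, CXCL3 at 5.90 and 10.56, and TNFAIP3, a feedback inhibitor of NF-kB, at 9.08 and 12.45. The 2 transdetermined arrays lay at 10.27 and 9.40 for CXCL8 and at 9.76 and 9.21 for TNFAIP3, between or near the olfactory values. CXCL6 was at 5.18 and 8.33 on the olfactory arrays and at 11.47 and 11.36 on the transdetermined arrays (adjusted p = 0.0575). These genes were picked after their values were seen.

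PTPRC and CD14 rose while most leukocyte genes stayed dim. Leukocytes mixed into the transdetermined cultures would bring their other abundant transcripts. The other 25 genes of the pan-leukocyte and myeloid list had a median change of -0.09 (95% bootstrap interval over genes from -0.15 to -0.07), and 1 of them rose. These values restate the pattern that prompted the question, so they are no separate test of an admixture. Of the 27 measured list genes 22 were dim, and CD33, FCGR3A and CD68 were not measured. A single cross-hybridising probe set is argued against for PTPRC, where 3 of 5 probe sets rose by at least 2 on the log2 scale in both arrays. For CD14 it stays open, since there was 1 probe set, and 1 of 1 rose. A hypothesis that stays open is that the transdetermined cells may themselves transcribe these 2 genes without the rest of a leukocyte programme, which 4 arrays of mixed RNA cannot show cell by cell.

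Of 26 measured interferon-induced genes 14 rose and 12 were not past the threshold, and the list as a whole, called with the preset correlation, was not called with an estimated one (adjusted p = 0.496) or with fry (0.0822). A difference in 5' signal between arrays, from the RNA or its labelling, could in principle move these genes. The arrays of opposite groups with the closest 5' minus 3' control levels were olfactory replicate 1 and transdetermined replicate 2 (0.35 apart). Between these 2 arrays the median of the list still differed by 2.64 (95% bootstrap interval over genes from 1.47 to 3.33). That argues against 5' signal as the whole cause. The remaining pairs gave 2.68 with transdetermined replicate 2, and 1.65 and 1.87 with transdetermined replicate 1. Interferon gamma as the main inducer was looked at through genes that lean to one type of interferon, and the class II gene CD74 rose. The 14 genes that lean to type I interferon had a median change of 3.27 and 14 that lean to gamma one of 0.03. The difference was 3.24 (interval over genes from 2.31 to 3.82). Both intervals treat genes as independent and hold no spread between arrays, so they understate the uncertainty. The rise of the type I-leaning genes restates the result that prompted the question. Of the gamma-leaning genes 1 rose, and how many of them were dim was not counted, so low signal could hide a rise. The values lean against interferon gamma as the main inducer but do not exclude it. Whether the cultures themselves transcribed an interferon cannot be told apart from an outside source, since 0 of 18 measured interferon genes rose and all 18 were dim. The treatment of the cultures, which is not given in the sources used here, and an infection or other exposure of the transdetermined cultures were not tested.

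Genes that rose lay next to each other in gene order more often than chance. Among 16505 measured protein-coding genes, 42 neighbouring pairs had both members risen against 13.4 expected from 10000 permutations within classes of level (p = 1e-04, the smallest they can give, adjusted p = 0.000133 over 4 counts), and 25 pairs had both fallen against 5.6 (same p). Neighbours of the same gene family, such as the OAS, MX and PSG genes, account for part, whether through shared probes or shared regulation. Without pairs that share a symbol root, 28 risen pairs remained, above the permuted 95th percentile of 19, and 20 fallen pairs against 5.4 expected. Roots were cut at the first digit or hyphen, so a family pair such as PTPRB with PTPRR still counts among the 20. Examples are HHEX with EXOC6, COL15A1 with GALNT12, and the fallen run of DLX2, ITGA6, PDK1 and MAP3K20, picked after their values were seen. That run depends on PDK1, whose call was lost with the mean of all probe sets (log2 change -0.86, limma, adjusted p = 0.0562). The PDK1 call was also lost when any 1 array was left out, with log2 changes from -1.18 to -1.52. Shared regulation, transcripts that run into the next gene, and a change in gene copy number in one of the cultures could each place changed genes side by side and were not tested.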
